A study of Canis lupus familiaris with 4 samples.

How the data were processed

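Single-cell RNA was measured in 4 libraries from 1 Beagle dog. Per the labels, mandibular premolars were extracted on both sides, the left side carried a peri-implantitis model and the right side served as the healthy control, and tissue was taken after 8 weeks. Gingiva and alveolar bone were digested separately with collagenase type I at 3 mg/mL and dispase II at 4 mg/mL for 60 minutes at 37 °C, per the labels. Red cells were lysed and the suspension passed a 40 µm strainer, per the labels, and libraries were made with the 10x 3' kit, version 3, and read at 150 bp. The groups were healthy gingiva, peri-implantitis gingiva, healthy alveolar bone and peri-implantitis alveolar bone, with 1 library each. Side and condition are the same split in this design, and the labels do not make clear whether the control side carried implants. The protocol text in the labels states approximately 35000 cells and in the same phrase sorted cells, without saying whether that number is per library or whether any library was sorted.

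The deposited matrices hold raw UMI counts per gene and cell barcode, which are unnormalised, and per the file headers they were written by Cell Ranger 6.0.2. Their barcodes were taken to be called cells, and how they were called was not checked. The processing notes in the labels name the mouse build mm10, whereas the 21823 feature names in the deposited files are dog symbols, of which 20947 occur in the RefSeq gene table used here and 3765 are LOC numbers. The dog build behind the counts is not stated, so no coordinates are given. None of the features (0) is a mitochondrial gene, so no filter on mitochondrial UMIs was applied.

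Libraries held 6460 (healthy gingiva), 13019 (peri-implantitis gingiva), 6522 (healthy bone) and 10239 (peri-implantitis bone) barcodes, 36240 in all. Barcodes with at least 200 detected genes were kept. Doublets were scored per library with Scrublet in scanpy 1.11.5 and removed above the automatic threshold. Where that marked under 0.5% of barcodes, the highest scores were removed at 0.8% per 1000 barcodes. The automatic threshold removed 107, 70 and 86 barcodes in peri-implantitis gingiva, healthy bone and peri-implantitis bone. In healthy gingiva it marked 2 barcodes, so the rate applied there and removed 334, which is 5.17% against 0.82% to 1.07% in the other 3 libraries. The kept cells were 6126, 12911, 6425 and 9929 in the order above, 35391 in all.

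Cells of all 4 libraries were clustered together without integration. Counts were scaled to 10000 per cell and log-transformed, 2000 variable genes were scaled and clipped at 10, and 40 principal components and 20 neighbours were used for Leiden clustering at resolution 1 (igraph 0.11.9, anndata 0.12.19, scikit-learn 1.9.0). This gave 41 clusters. A cluster took the class whose fixed markers had the highest mean log2 level over the median cluster, out of 25 marker lists written before the data were examined. It needed at least 3 markers at 50 CPM and 2-fold over the median cluster and a mean marker fold of 2, and it stayed unnamed when its top 10 genes held more markers of another class. This gave 15 named classes, written here with the ending "-like". After the data were examined a rule was added for clusters with a median depth under 50% of that of their library. Such a cluster stayed unnamed when its best class led a class of another compartment by under 0.75 on the log2 scale. That rule left 3 clusters unnamed, which held 24.9% and 1.63% of the cells of peri-implantitis gingiva and 5.60% of the cells of peri-implantitis bone. In all, 7 clusters were unnamed.

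Class shares are percentages of kept cells with exact Clopper-Pearson 95% intervals, and differences between shares carry Newcombe 95% intervals. Within a class, UMIs were summed per library and expressed as CPM, the UMIs of a gene scaled by the total of that sum, with exact Poisson 95% intervals. Ratios are log2 of (CPM + 10) in the second library over (CPM + 10) in the first, for classes of at least 100 cells in both libraries. All intervals cover counting error only. With 1 library per group from 1 animal there is no replicate, so no test was run and no p-value is given, and cells were not treated as replicates. The same exact intervals give the upper limit where a count was 0.

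Named genes follow a rule written before the data were examined. In each tissue, the 5 classes with the most cells in the smaller library were used. In each, the 3 genes with the largest and the 3 with the smallest ratio were named, among genes with a symbol, at least 50 CPM and 20 UMIs in the higher library, Poisson intervals that do not overlap, and a level of at least 10% of that in the highest class of the same library. Not every gene that meets the rule is described. The highest class was first sought among classes of at least 100 cells. After the first result was seen this became classes of at least 20 cells, which took a few genes of rarer cells off the lists for lymphoid classes.

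Fixed gene lists, 35 in all, were written before the data were examined. A list was summarised in a class by the median log2 ratio of its members with at least 10 CPM in either library, if at least 3 were measured. The median was set beside those of 10000 random lists of equal size matched on mean expression in 20 bins, and members at least 2-fold higher or lower were counted. The random lists describe these libraries, and they are no test. The lists described by name in the report were chosen after their medians were seen, so the number of lists above and below the random lists is given for each class. The members named are among those with the largest ratios.

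Free RNA was estimated per class and library as the median, over markers of other compartments with at least 100 CPM in the library, of the class level over the library level, in percent. The calculations ran in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9.

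The ratio step was tested on simulated data. In 4 class pairs, 200 genes were given known changes at the observed depths. Of the genes changed 2-fold, 100% were recovered with intervals that do not overlap in fibroblast-like and T cell-like cells of gingiva and T cell-like cells of bone, and 94.2% in neutrophil-like cells of bone. All genes changed 4-fold were recovered. Among genes left unchanged, 4.23% to 12.83% had intervals that do not overlap, in part because the raised genes lower the CPM of the rest. Of 100 unchanged lists per pair, 1 to 4 lay outside the random lists. The counts were drawn with Poisson error alone from the healthy profile, without free RNA, differences between clusters or genes that vary together. These numbers therefore test the code, and they do not tell how often lists fall outside in real libraries.

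Alternatives were tried for the gene minimum (500), doublets, resolution (0.5 and 2), clustering of each library on its own, 4000 variable genes and the denominator of shares. For ratios they were TMM and median-of-ratios scaling, a pseudocount of 1, a list minimum of 50 CPM or none, cells thinned to 1000 UMIs, and a mean over cells. The naming margin, shares of named cells, free RNA taken off, and list members restricted to 10% of the highest class were added after the data were examined. Alternatives on mitochondrial UMIs were not run, for want of such features. Classes under 100 cells in either library of a pair were left out of the ratios.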

Results

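Gene expression was measured in single cells of gingiva and alveolar bone from 1 Beagle dog, with 1 library from the peri-implantitis side and 1 from the healthy control side for each tissue. The libraries held 60525018 UMIs in 6460 barcodes (healthy gingiva), 111890710 in 13019 (peri-implantitis gingiva), 28613318 in 6522 (healthy bone) and 114774465 in 10239 (peri-implantitis bone). Median UMIs per barcode were 5144, 2944, 2414 and 6913 in that order, and median detected genes were 1761, 1174, 856 and 1653. The smallest barcode held 929 UMIs in peri-implantitis gingiva and 500 in the other 3 libraries. The barcodes number 36240 in all, beside approximately 35000 cells in the protocol text, which leaves open whether that number is per library and whether cells were sorted. There is no replicate. Differences are described by size, and every interval is a 95% interval for counting error only.

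Cells fell into 15 named classes. Epithelial-like clusters were named from markers that include keratins such as KRT5 and KRT14. The markers include collagen genes and DCN for fibroblast-like, PECAM1 and CDH5 for endothelial-like, and RGS5 and ACTA2 for mural-like clusters. Osteoblast lineage-like cells were named from bone matrix genes such as IBSP, neutrophil-like cells from CSF3R and CXCR2, and plasma cell-like cells from JCHAIN and MZB1. The osteoblast lineage-like cells all lay in cluster 36. Its mean log2 marker level was 4.25 for osteoblast lineage and 4.13 for fibroblast markers, so its name rests on a narrow lead. The NK and cytotoxic-like cells all lay in cluster 12, with a mean log2 level of 4.87 for their own and 3.82 for T cell markers. CD3E was among its top 10 genes, and NCR1 was at 5.4 CPM or less in each library. NK cells and cytotoxic T cells are therefore not told apart in this class. Several clusters had stress or immune genes among their top 10 genes. These were MT1E in the main T cell-like cluster of healthy bone, and PTX3 and SAA1 in the main fibroblast-like cluster of peri-implantitis bone. In peri-implantitis gingiva they were MMP12 and MMP1 in the main fibroblast-like cluster and SLPI in the main epithelial-like cluster. The cluster with the most cells of a class differed between the compared libraries for T cell-like, B cell-like and neutrophil-like cells in both tissues and for epithelial-like, endothelial-like and fibroblast-like cells in gingiva, so differences within these classes are also differences between clusters. Of the fibroblast-like cells, cluster 5 held 99.9% of those from healthy gingiva and cluster 26 held 81.3% of those from peri-implantitis gingiva. For epithelial-like cells these were cluster 3 with 55.4% and cluster 33 with 56.7%, and for endothelial-like cells cluster 0 with 39.3% and cluster 8 with 78.8%. Cluster 3 was named weakly, from 6 epithelial markers with 0 in its top 10 genes. Its mean log2 marker level was 1.55 for epithelial and 1.27 for neutrophil markers.

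The first comparison asks how the cell content of gingiva differs between the peri-implantitis and the healthy side. Inflamed gingiva held more neutrophil-like and plasma cell-like cells, and smaller shares of endothelial-like, T cell-like and B cell-like cells. The epithelial-like share was smaller too, but that direction turned with how cells were grouped. Neutrophils are the first leukocytes to enter infected tissue, and plasma cells secrete antibody. Mural-like cells, which wrap small vessels, also made up a larger share.

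Neutrophil-like cells were 1.98% of healthy and 10.9% of peri-implantitis gingiva, a difference of 8.95 percentage points (8.30 to 9.58). Plasma cell-like cells were 1.37% and 8.13%, a difference of 6.76 points (6.2 to 7.31). Mural-like cells were higher by 3.48 points (2.79 to 4.15). For endothelial-like cells the difference was -11.8 points (-13.1 to -10.6), though from -17.1 to -2.42 points over the alternatives. The smallest barcode held 500 UMIs in healthy and 929 in peri-implantitis gingiva. Of the endothelial-like cells, 500 of 1582 in healthy and 38 of 1806 in peri-implantitis gingiva held under 1000 UMIs. With cells of at least 1000 UMIs, endothelial-like cells were 1082 of 5296 in healthy and 1768 of 11869 in peri-implantitis gingiva. That comparison was made after the result was seen. The share was still lower on the peri-implantitis side, but by less than among all kept cells. Part of this difference thus goes with shallow cells, which the unequal floors admit unequally. The difference was -6.98 points (-7.85 to -6.14) for T cell-like, -5.30 points (-5.95 to -4.69) for B cell-like, -1.62 points (-2.0 to -1.29) for lymphatic endothelial-like and -1.18 points (-1.63 to -0.766) for NK and cytotoxic-like cells. For macrophage and monocyte-like cells the difference of 0.229 points (-0.161 to 0.586) was not detectable at this depth, nor was that of 0.069 points (-0.016 to 0.138) for mast cell-like cells. Schwann-like, osteoclast-like and osteoblast lineage-like cells differed by 0.193, 0.201 and 0.325 points. Haematopoietic classes together were 24.6% and 27.3%, a difference of 2.75 points (1.42 to 4.07), but 24.8% and 38.0% of the cells in named classes, a difference of 13.2 points.

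Epithelial-like cells were 31.7% and 13.5%, a difference of -18.2 points (-19.5 to -16.9), and fibroblast-like cells were 11.0% and 8.76%, a difference of -2.21 points (-3.15 to -1.30). Both directions depend on how cells were grouped. The epithelial-like difference was 0.685 points with each library clustered on its own and 6.63 points with the naming margin off. The fibroblast-like difference was above 0 under 6 alternatives, for example 1.82 points at resolution 2. Unnamed cells were 0.963% of healthy and 28.1% of peri-implantitis gingiva, so shares of the other classes in the latter are shares of a total that includes them.

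In bone, the comparison between sides showed a different exchange of cells. Healthy bone was rich in neutrophil-like cells, as marrow usually is, while peri-implantitis bone held plasma cell-like, fibroblast-like, macrophage-like and osteoclast-like cells in their place. Osteoclasts resorb bone. Endothelial-like, mural-like and B cell-like cells were scarcer on the peri-implantitis side. Mast cell-like cells, a class of uncertain identity, were scarcer too, though that direction turned with the removal of doublets. T cell-like cells made up about the same share on both sides in the main clustering, and the sign of their difference turned with the processing.

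Neutrophil-like cells were 41.2% of healthy and 4.61% of peri-implantitis bone, a difference of -36.5 points (-37.8 to -35.3). Plasma cell-like cells were 0.498% and 25.4%, a difference of 24.9 points (24.0 to 25.8), and fibroblast-like cells 0.840% and 20.8%, a difference of 19.99 points (19.2 to 20.8). The fibroblast-like difference was 7.46 points with each library clustered on its own, 11.5 points at resolution 2 and 71.8 points among non-immune cells. The difference was 6.16 points (5.64 to 6.70) for macrophage and monocyte-like and 1.66 points (1.34 to 1.98) for osteoclast-like cells, which were 0.358% and 2.01%. It was -5.68 points (-6.33 to -5.07) for endothelial-like, -5.10 points (-5.76 to -4.48) for B cell-like, -1.61 points (-1.97 to -1.28) for mural-like, -0.514 points for Schwann-like and -0.374 points for lymphatic endothelial-like cells. Mast cell-like cells were 2.49% of healthy bone and 0 of 9929 cells in peri-implantitis bone, which allows a share of up to 0.037%. With doublets removed by rate in every library the difference was 0.437 points instead of -2.49. This class rests on 3 markers, the fewest allowed. In healthy bone it held MS4A2, CPA3 and FCER1A at 1037, 501 and 348 CPM, but KIT, HDC and HPGDS at 0.0 CPM. Its identity as mast cells is therefore uncertain. For T cell-like cells the difference of -0.235 points (-1.53 to 1.05) in the main clustering was not detectable at this depth. With the higher gene minimum per cell it was -4.33 points, and among immune cells 4.36 points, so its sign depends on the processing. All haematopoietic classes together were 75.3% and 64.7%.

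Osteoblast lineage-like cells were 11.9% and 5.35%, a difference of -6.54 points (-7.46 to -5.65), but 2.08 points at resolution 2 and 3.59 points with each library clustered on its own, and no cluster took that name with doublets removed by rate in every library. Fibroblast-like and osteoblast lineage-like cells as 1 class were 12.7% and 26.2%, a difference of 13.4 points (12.2 to 14.6). It kept its sign under every alternative, but this class also took in any cells that an alternative named marrow stromal-like. No main cluster had that name. NK and cytotoxic-like cells were higher by 1.06 points (0.556 to 1.55), but the difference was -0.832 points at resolution 0.5, -0.807 at resolution 2 and -0.671 with each library on its own. Epithelial-like cells differed by 0.277 points and unnamed cells by 5.04 points.

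**Figure D1:**
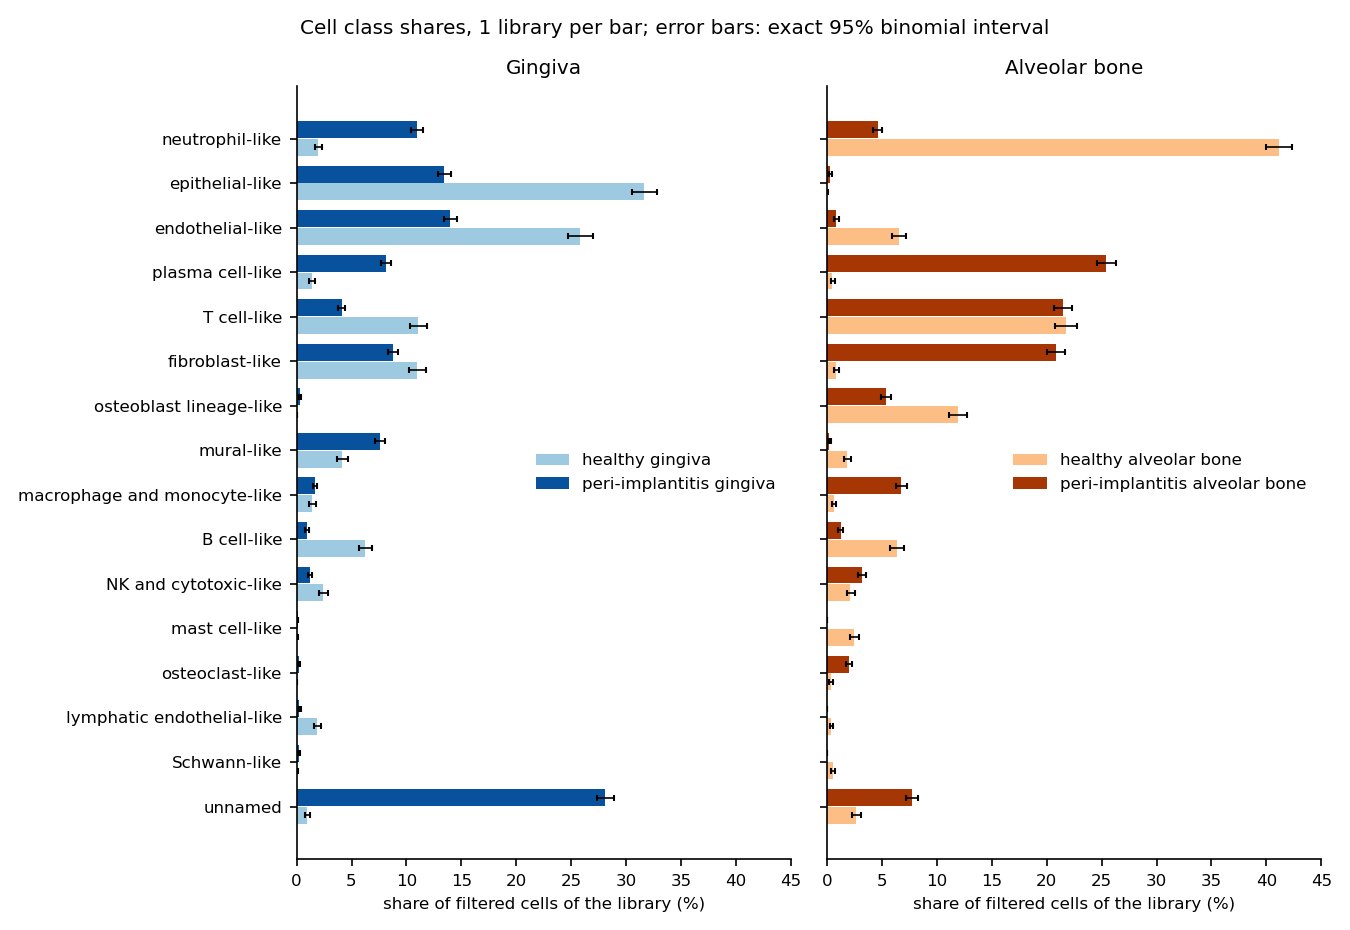
Share of kept cells (percent, x axis) in each class for the 4 libraries, with bars for shares and error bars for exact 95% intervals. Neutrophil-like cells were 10.9% against 1.98% in gingiva and 4.61% against 41.2% in bone (peri-implantitis against healthy), and plasma cell-like cells were higher on the peri-implantitis side in both tissues.

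Transcripts of other cell compartments were counted in every class, and more of them in peri-implantitis libraries. The estimated share of such free RNA had a median over classes of 8.43% in healthy gingiva, 19.1% in peri-implantitis gingiva, 2.10% in healthy bone and 8.83% in peri-implantitis bone. Doublets left in a class would raise this estimate too. Removal took 5.17% of barcodes in healthy and 0.82% in peri-implantitis gingiva, where the rate would have taken 10.42%. How much of the estimate comes from doublets was not tested. In neutrophil-like cells of gingiva it was 15.9% and 41.0%, and in T cell-like cells 9.12% and 23.3%. The number of gene lists above the random lists includes lists of other cell types, such as keratin and matrix lists in lymphoid classes of peri-implantitis gingiva and plasma cell and matrix lists in classes of peri-implantitis bone. With free RNA taken off, wound and stress keratins still lay above the random lists in B cell-like (2.52), NK and cytotoxic-like (1.40) and T cell-like cells (1.76) of gingiva, and matrix crosslinking genes in the first 2 (0.78 and 1.02), over 3 to 6 members, so the estimate does not account for all of them. Ratios below were repeated with free RNA taken off, and changes are named where that matters.

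**Figure D2:**
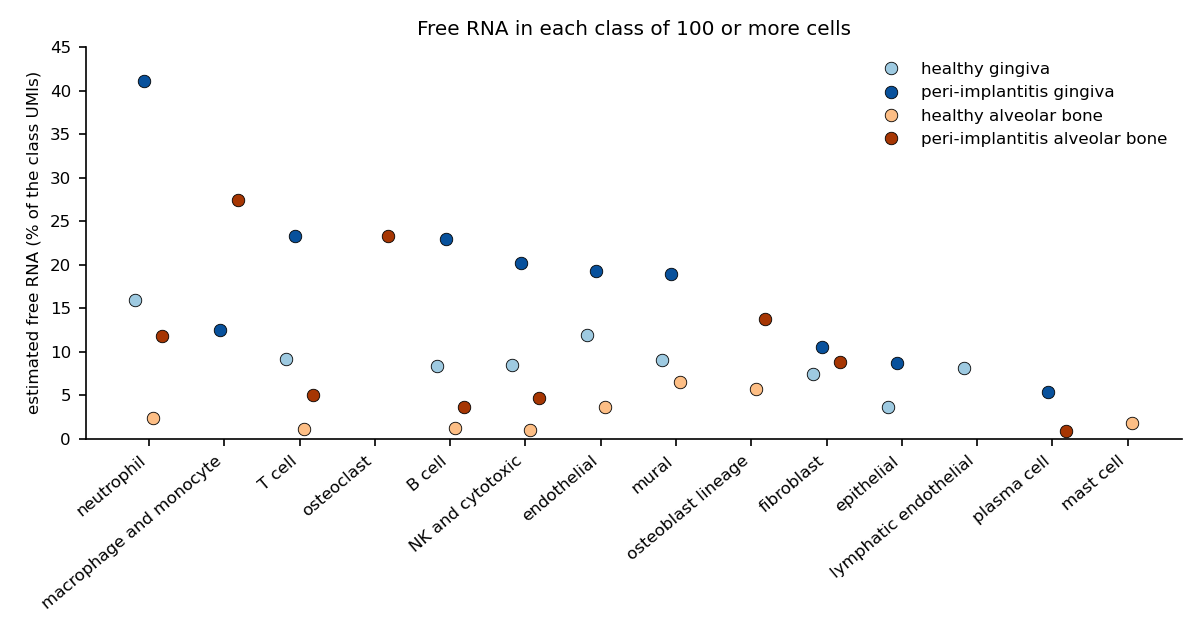
Estimated free RNA (percent of a class's UMIs) for each class of at least 100 cells in the 4 libraries. Medians over classes were 8.43% and 19.1% in healthy and peri-implantitis gingiva and 2.10% and 8.83% in bone.

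Within gingival epithelial-like cells, most wound keratins and basal keratinocyte genes were higher on the peri-implantitis side, and several differentiation genes were lower. SLPI encodes a secreted inhibitor of neutrophil elastase, CRYAB a small heat-shock protein and KRT16 a keratin induced in wounded epithelium. Lower were WFDC2, which encodes a secreted protein of the whey acidic protein family, and ASPRV1 and KLK13, proteases of stratified epithelium. SLPI was at 577 CPM (569 to 585) in healthy and 69625 CPM (69536 to 69714) in peri-implantitis cells, 121 times higher. The log2 ratio was 6.07 for CRYAB and 5.48 for KRT16, and -4.82 for WFDC2, -4.64 for ASPRV1 and -4.10 for KLK13. The wound and stress keratin list had a median log2 ratio of 2.44 over 7 measured members (random lists -1.10 to 0.74), with KRT17 at 5.12 and KRT6A at 3.43 but S100A8 at -1.37; 5 members were at least 2-fold higher and 2 lower. Basal keratinocyte genes had a median of 1.53 (random -0.37 to 0.61), with KRT14 at 2.32 and ITGA6 at 1.92. Differentiation and barrier genes had a median of -0.46 (random -0.27 to 0.56), led by TGM3 at -3.31 and KRT76 at -2.38, with CLDN1 at 43.9 and 206 CPM; 7 of 16 members were at least 2-fold lower and 1 higher. Glycolysis genes had a median of 1.10 (random -0.26 to 0.55), led by HK2 at 1.79. In this class 21 lists lay above and 2 below the random lists, of 31.

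Gingival fibroblast-like cells of the peri-implantitis side expressed enzymes that cut collagen and elastin, a chemokine that draws neutrophils, and the ligand that drives osteoclast formation. MMP12 encodes macrophage elastase, MMP1 and MMP13 encode collagenases, and CXCL8 encodes interleukin-8. TNFSF11 encodes RANKL. SPARCL1, the lymphoid chemokine CCL19, SPP2 and the complement genes C7 and CFD were lower. MMP12 had 3 UMIs in healthy cells, 0.6 CPM (0.1 to 1.7), and 167517 in peri-implantitis cells, 8825 CPM (8783 to 8867). MMP1 was 153 times higher, at 49.3 and 7531 CPM. CXCL8 had a log2 ratio of 6.38, though at 12.8% of its level in the highest class of that library. The ratios of SPP2, CCL19 and SPARCL1 were -4.13, -4.10 and -4.07.

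Lists placed these genes in wider programs of the same cells. Matrix metalloproteinases and inhibitors had a median of 1.5 (random -0.33 to 0.36), with MMP11 at 3.83 and TIMP3, an inhibitor, at -3.27; MMP13 was at 0.4 and 389 CPM from 2 and 7379 UMIs. Pro-inflammatory cytokines had a median of 1.17 over 7 members (random -0.55 to 0.40), with CSF3 at 3.58 and IL6 at 2.62. Glycolysis genes had a median of 1.12 (random -0.36 to 0.29), with PFKFB3 at 3.00 and SLC2A3 at 2.33. TGF-beta and BMP response genes had a median of 0.92 (random -0.37 to 0.26), with INHBA at 3.08 and BAMBI at 2.05. Complement genes had a median of -0.95 (random -0.38 to 0.43), with C7 at -3.22 and CFD at -2.20. The osteoclast-regulating ligands had a median of -0.90 over 6 members (random -0.58 to 0.49) and a mean of 0.385, so median and mean differ in sign, and a median of 0.094 with members of 50 CPM or more. Their member TNFSF11 was higher at 5.03, from 2.1 to 386 CPM, WNT5A was at 1.06 and SEMA3A at -1.06. In this class 11 lists lay above and 2 below, of 32.

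Endothelial-like cells of peri-implantitis gingiva carried more collagen transcripts, by a list that joins fibrillar and basement-membrane collagens. ADAMTS5 encodes an aggrecanase and DNASE1L3 a secreted nuclease. In endothelial-like cells their log2 ratios were 3.15 and 2.81, while those of APOE, ZBTB16 and IFGGC1 were -2.45, -2.23 and -1.99. Collagens had a median of 1.04 (random -0.18 to 0.22), led by COL4A1 at 2.53 and COL4A2 at 2.25, and COL5A2 at 1.88 went to -0.18 with free RNA taken off. TGF-beta and BMP response genes had a median of 0.96 (random -0.17 to 0.24), with LTBP1 at 1.26 and ID1 at 1.20. Interferon response genes had a median of -0.31 (random -0.11 to 0.18), with GBP1 at -1.35 and ISG15 at -1.25. Here 15 lists lay above and 2 below, of 31.

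Mural-like cells of peri-implantitis gingiva showed collagen and cell-cycle genes. COL15A1 was at 2.8 and 144 CPM, a log2 ratio of 3.58, and RARRES1 at 3.21. TOP2A, which encodes a topoisomerase of dividing cells, had 1 and 745 UMIs, 0.7 CPM (0.0 to 4.0) and 93.0 CPM (86.5 to 99.9). CCL19 had 157 and 1 UMIs, 112 CPM (94.9 to 130.5) and 0.1 CPM (0.0 to 0.7), and APOE and OGN had ratios of -3.55 and -3.02. Collagens had a median of 2.08 (random -0.39 to 0.23), with COL1A1 at 2.74 and COL4A1 at 2.55. Proliferation genes had a median of 1.11 (random -0.27 to 0.18), with CENPF at 1.4 and 78.9 CPM and MKI67 at 1.4 and 41.5 CPM. Here 19 lists lay above and 2 below, of 31.

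Gingival T cell-like cells of the peri-implantitis side lacked most transcripts of CXCL13, the chemokine of B cell follicles. CXCL13 had 252 and 2 UMIs, 74.8 CPM (65.9 to 84.6) and 0.7 CPM (0.1 to 2.6). IFGGB2 had a log2 ratio of -1.58. CPA3, a mast cell gene, was at -1.56 but at 0.70 with each library clustered on its own. The higher genes KRT16, PI3 and GJB2, at 3.28, 2.56 and 2.48, belong to keratinocytes and stood at 10.7% to 14.5% of their level in the highest class, so free RNA is open as their source. T-cell helper genes had a median of -0.26 (random -0.21 to 0.15), and -0.08 with free RNA taken off, with CXCR5 at -1.57 and IL23R at 1.00. IL17A, a cytokine of helper T cells, was at 34.4 CPM (28.5 to 41.3) and 62.2 CPM (53.3 to 72.3). Neutrophil granule genes in gingival neutrophil-like cells had a median of -1.31 (random -0.43 to 0.41), and -1.04 with free RNA taken off, with CAMP at -3.73, CD177 at -3.01 and LCN2 at -1.85. The abundant members S100A8 and S100A9 hardly differed, at 21188 and 21983 CPM and at 26006 and 26164 CPM. Healthy gingiva held 121 neutrophil-like cells. Lists of other cell types differed in these cells too, among them wound and stress keratins at 2.67 (random -0.49 to 0.54), and 1.53 over 6 members with free RNA taken off. The numbers of lists above and below were 22 and 1 of 33 in T cell-like, 21 and 1 of 33 in NK and cytotoxic-like, 21 and 1 of 32 in B cell-like and 13 and 2 of 31 in neutrophil-like cells.

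**Figure D3:**
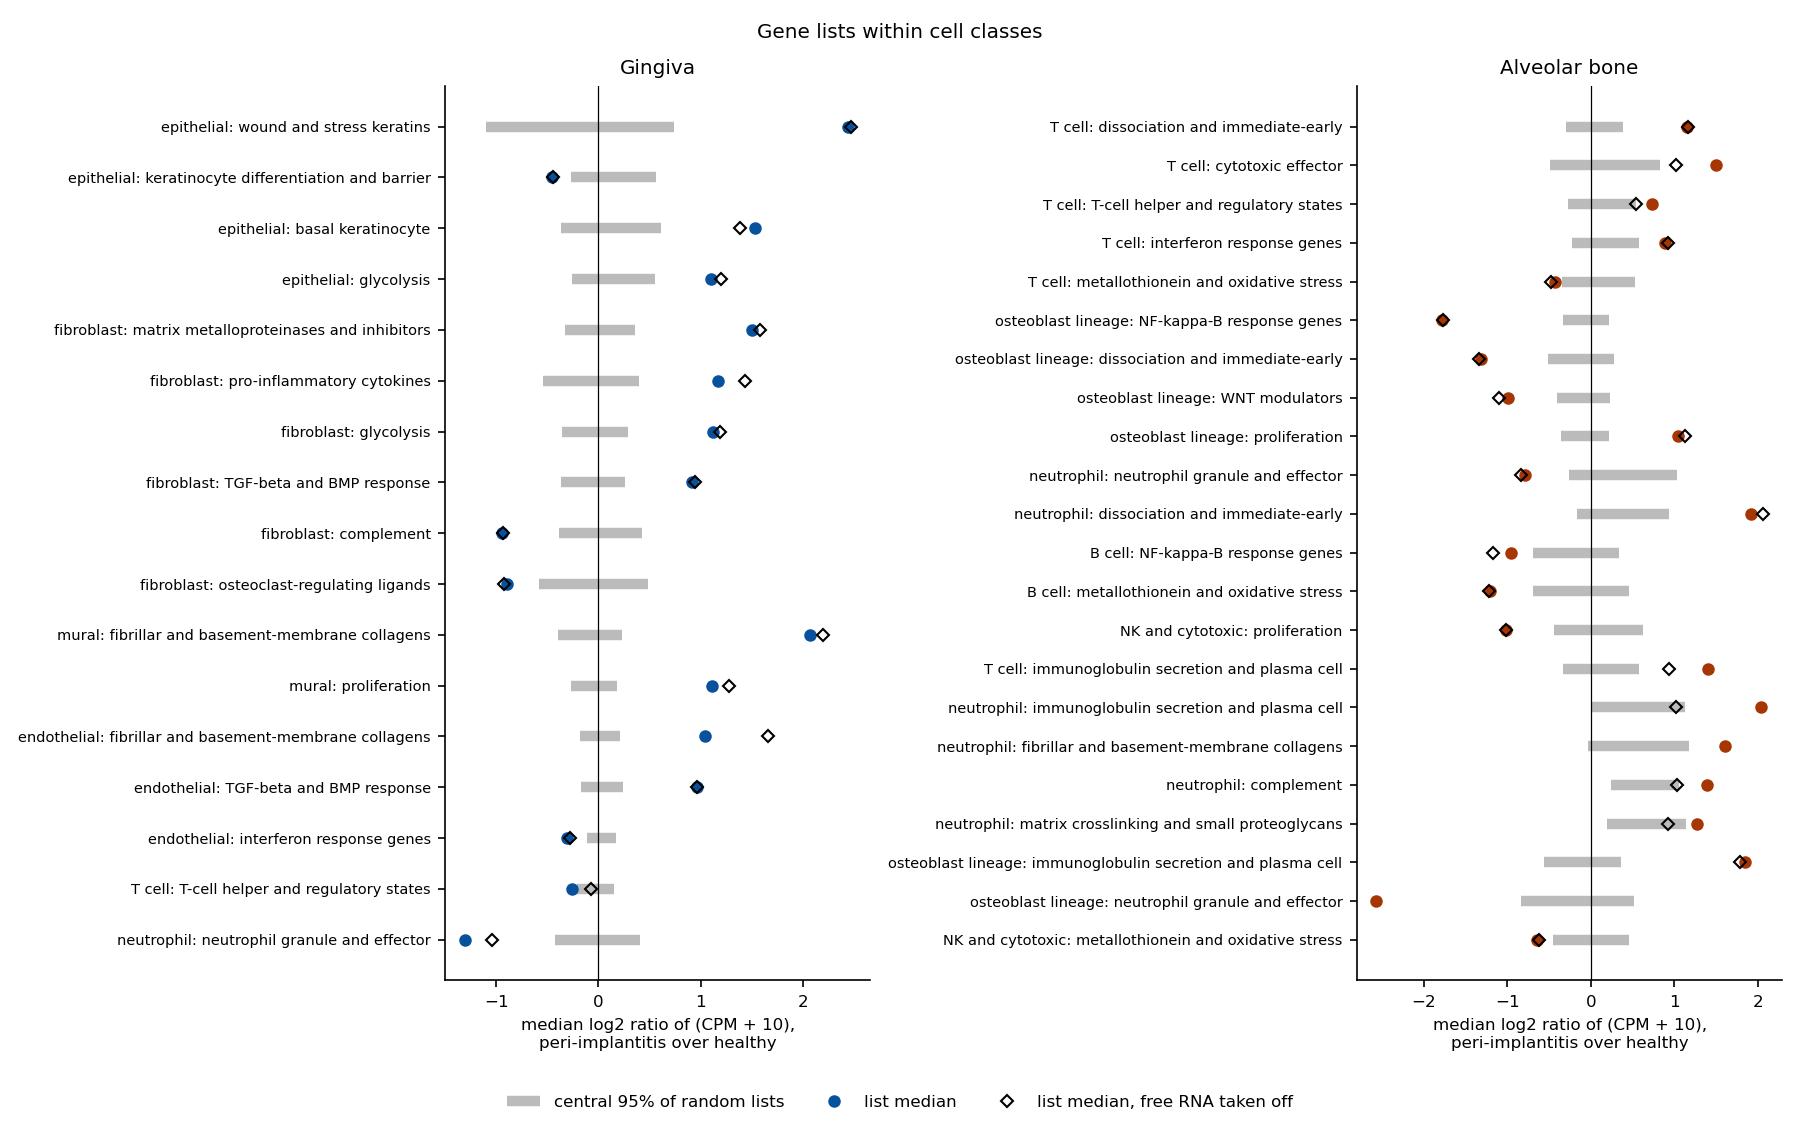
Median log2 ratio (peri-implantitis over healthy) of the gene lists described, by class and tissue, as counted (filled points) and with free RNA taken off (open points), beside the central 95% of random lists (grey bars). For example, the median was 2.44 for wound and stress keratins in gingival epithelial-like cells and -2.57 for neutrophil granule genes in osteoblast lineage-like cells of bone.

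In bone, the lymphoid classes of the healthy side were rich in metallothionein transcripts, which encode metal-binding proteins, and in GLRX, which encodes glutaredoxin. T cell-like cells of peri-implantitis bone carried more heat-shock and immediate-early transcripts. MT1E was at 18229 CPM (18141 to 18317) in healthy and 217 CPM (205 to 229) in peri-implantitis T cell-like cells, and the log2 ratios of MT1E, MT2A and GLRX were -6.33, -5.11 and -4.74. HSP70, LRRC71 and FOS were at 3.11, 2.94 and 2.74. Dissociation and immediate-early genes had a median of 1.15 (random -0.30 to 0.39), with DUSP1 at 2.62. The cytotoxic effector list had a median of 1.49 over 5 members (random -0.49 to 0.82), with KLRB1 at 2.10 and GZMK at 1.64; these stood below 10% of their level in the highest class, and the median was 1.02 over 6 members with free RNA taken off (random -0.40 to 0.76) but 0.085 without the filter on low values, and fewer than 3 members stood at 10% or more of their level in the highest class. Helper and regulatory genes had a median of 0.73 (random -0.27 to 0.54) with 6 of 14 members at least 2-fold higher and 3 lower, with IKZF2 at 2.26 and CCR6 at 2.11, and IL17A at 3.1 and 40.7 CPM. Interferon response genes had a median of 0.89 (random -0.23 to 0.57), with GBP1 at 1.53. The metallothionein and oxidative stress list had a median of -0.43 (random -0.34 to 0.53), with CAT at 1.35. Plasma cell genes had a median of 1.41 (random -0.34 to 0.58), and 0.93 with free RNA taken off. The helper, interferon and metallothionein lists came within the random lists under some alternatives. Here 11 lists lay above and 5 below, of 29.

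Metallothionein transcripts were also lower in B cell-like and NK and cytotoxic-like cells of peri-implantitis bone. In B cell-like cells the ratios of MT1E and MT2A were -6.86 and -4.96, and CFAP46 had 290 and 0 UMIs, 148 CPM (131 to 166) and 0.0 CPM (0.0 to 10.8). TNFRSF13B and BTLA, receptors of B cells, were at 3.07 and 2.74. HBM, a haemoglobin gene, had 0 and 36 UMIs; no red-cell class formed, so free RNA is open as its source. NF-kappa-B response genes had a median of -0.96 (random -0.70 to 0.34), with REL at -2.21 and RELB at -1.74, and the metallothionein and oxidative stress list had one of -1.21 (random -0.70 to 0.46). In NK and cytotoxic-like cells MT1E, GLRX and MT2A were at -6.22, -5.77 and -4.97, and IL7R and CD160 at 2.97 and 2.87. LRRC71 had 0 and 76 UMIs, the latter 82.3 CPM (64.8 to 103.0). The metallothionein and oxidative stress list had a median of -0.65 (random -0.46 to 0.46), which came within the random lists with members of 50 CPM or more. Proliferation genes had a median of -1.02 (random -0.45 to 0.62), with PCNA at -1.91. Lists above and below were 8 and 6 of 26 in B cell-like and 9 and 4 of 30 in NK and cytotoxic-like cells.

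Neutrophil-like cells of peri-implantitis bone had more TSC22D3, a glucocorticoid-induced gene, and lower levels of several granule and effector genes. TSC22D3, RERE and ADAM19 were at 3.94, 3.88 and 3.85. PWP1 and MUC4 were at -4.47 and -4.38, and JMY had 1937 and 2 UMIs, 405 CPM (387 to 423) and 4.1 CPM (0.5 to 14.7). Granule and effector genes had a median of -0.79 (random -0.27 to 1.03), with NCF1 at -2.68 and CAMP at -2.12. Of 13 measured members 6 were at least 2-fold lower and 0 higher. Not all were lower, since S100A9 was at 17058 and 24315 CPM and LTF at 673 and 781 CPM in healthy and peri-implantitis bone. Dissociation and immediate-early genes, which also respond to tissue handling, had a median of 1.92 (random -0.17 to 0.93), with ZFP36 at 3.18 and SOCS3 at 3.17 and 12 of 18 members at least 2-fold higher. The other 4 lists above the random lists hold genes made mainly by other cell types. These were plasma cell genes at 2.04 (random 0.00 to 1.12), collagens at 1.60 (random -0.04 to 1.18), complement at 1.39 (random 0.24 to 1.06) and matrix crosslinking genes at 1.28 (random 0.20 to 1.13). With free RNA taken off, the plasma cell, complement and matrix crosslinking lists came within the random lists, at 1.02, 1.03 and 0.92, and the collagens had too few members left. The median of all genes in this class was 0.725, and TMM scaling moved ratios by -1.23 here. Lists above and below were 5 and 6 of 29.

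Osteoblast lineage-like cells of peri-implantitis bone had lower NF-kappa-B, dissociation and immediate-early, and WNT-modulator genes than those of healthy bone. Their cluster had fibroblast markers almost as high as osteoblast lineage markers (4.13 and 4.25), so the class is not cleanly set apart from fibroblast-like cells. SAA1, an acute-phase gene, had 0 and 3222 UMIs, the latter 551 CPM (532 to 570), and MAL had 1 and 517 UMIs, 0.2 CPM (0.0 to 1.1) and 88.3 CPM (80.9 to 96.3). TXNDC5, also a plasma cell gene, was at 3.04. SAA1, MAL and TXNDC5 stood at 20.4%, 15.1% and 19.6% of their level in the highest class, and 13.8% of the UMIs of these cells were estimated as free RNA. With it taken off SAA1 and MAL were at 532 and 89.7 CPM in peri-implantitis cells, and TXNDC5 had a ratio of 2.49. ADAMTS1, IRF1 and RGS16 were at -3.92, -3.90 and -3.78. NF-kappa-B response genes had a median of -1.79 (random -0.33 to 0.21), with REL at -2.36 and NFKBIA at -2.15. Dissociation and immediate-early genes had a median of -1.32 (random -0.52 to 0.28), with ATF3 at -2.73 and 14 of 18 members at least 2-fold lower. Lists of other cell types differed by as much in these cells. Plasma cell genes had a median of 1.85 (random -0.56 to 0.37), and 1.79 with free RNA taken off, and neutrophil granule genes one of -2.57 over 5 members (random -0.83 to 0.51), too few of which were left with free RNA taken off. WNT modulators had a median of -0.99 (random -0.40 to 0.23), with SFRP4 at -1.51 and DKK1 at -1.42; SFRP1 at -1.76 and DKK3 at -1.35 turned to 0.40 and 0.23 with each library on its own. Proliferation genes had a median of 1.05 (random -0.36 to 0.21), with CENPF at 1.95 and UBE2C at 1.64, and 0.10 at resolution 2. The WNT-modulator list came within the random lists with members of 50 CPM or more. Lists above and below were 4 and 12 of 30. Elsewhere TMM scaling moved ratios by over 0.1 in gingival epithelial-like (-0.46) and fibroblast-like cells (0.24) and in T cell-like (-0.26), NK and cytotoxic-like (-0.11) and osteoblast lineage-like cells (0.10) of bone.

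Gingiva was also compared with bone on each side, to see whether the dissected tissues hold different cells and move alike. Epithelial-like and endothelial-like cells had larger shares in gingiva, and haematopoietic classes together and osteoblast lineage-like cells had larger shares in bone, while neutrophil-like cells had the larger share in bone on the healthy side and in gingiva on the other. On the healthy side gingiva minus bone was 31.7 points (30.5 to 32.8) for epithelial-like, 19.3 points (18.0 to 20.5) for endothelial-like and 10.1 points (9.33 to 10.96) for fibroblast-like cells. It was -39.2 points (-40.4 to -37.9) for neutrophil-like, -11.9 points for osteoblast lineage-like and -10.7 points for T cell-like cells. On the peri-implantitis side it was 13.2 points for epithelial-like, 13.1 for endothelial-like, 7.38 for mural-like and 6.31 (5.63 to 6.99) for neutrophil-like cells. It was -17.3 points for plasma cell-like, -17.4 for T cell-like, -12.1 for fibroblast-like and -5.10 for macrophage and monocyte-like cells. All haematopoietic classes made up 24.6% of healthy gingiva against 75.3% of healthy bone, and 27.3% against 64.7% on the peri-implantitis side. Within T cell-like cells 18 lists lay above and 1 below the random lists of 31 on the healthy side, and 21 and 0 of 33 on the peri-implantitis side. Keratin lists, which T cells should lack, are among those above.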

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

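Of the tests below, those of damaged epithelial cells, of doublets, of dilution and of free RNA taken off in peri-implantitis cells alone were chosen only after the result was seen.

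Classes whose share was higher on the peri-implantitis side in one tissue and lower in the other drew a closer look; the difference between tissues was not tested, since each group is 1 library. Neutrophil-like cells differed by 8.95 points (8.30 to 9.58) in gingiva and -36.5 points (-37.8 to -35.3) in bone. Mural-like cells differed by 3.48 and -1.61 points, and NK and cytotoxic-like cells by -1.18 and 1.06 points. Fibroblast-like cells differed by -2.21 and 19.99 points, epithelial-like cells by -18.2 and 0.277 points, osteoblast lineage-like cells by 0.325 and -6.54 points and Schwann-like cells by 0.193 and -0.514 points. The signs for epithelial-like and fibroblast-like cells in gingiva, and for osteoblast lineage-like and NK and cytotoxic-like cells in bone, turn with the clustering.

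The opposite differences of neutrophil-like cells were weighed against the unequal UMI floors and against dilution. With cells of at least 1000 UMIs in every library the share ratio, peri-implantitis over healthy, was 5.86 in gingiva (2.02% and 11.8%), which argues against the floors there. Both bone libraries have the same floor of 500 UMIs, so the bone ratio of 0.057 (43.1% and 2.45%) decides nothing; the minimum left out 233 of 458 neutrophil-like cells of peri-implantitis bone and 95 of 2644 of healthy bone. Without plasma cell-like, fibroblast-like and macrophage-like cells the bone ratio was 0.234 (42.0% and 9.81%), which argues against dilution by these 3 classes as the whole cause. A difference in how much marrow each bone piece held, in sorting or in dissection, and the condition itself, remain open and untested, with side and condition the same split.

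Cluster 25 held 3216 cells, 24.9% of peri-implantitis gingiva, with a median of 1097 UMIs. Of 43 class markers 97.7% (87.7 to 99.9) lay within 2-fold of their level in the other cells of that library, as droplets filled mostly with free RNA would show. In its 10 named classes 4.8% to 17.9% did. That contrast is partly built in, since a class was named from markers raised at least 2-fold. Cluster 25 stayed unnamed because its epithelial and fibroblast markers were within the margin. Damaged epithelial cells alone are argued against by the median markers of other compartments. These stood at 1.01 (vascular, 3 markers), 0.836 (stromal, 13) and 0.814 (haematopoietic, 15) of their level in the other cells, and the epithelial one at 1.15 (11 markers). The most raised genes without a LOC number were KRTDAP, KRT24 and RHCG, at log2 ratios of 1.39, 1.1 and 0.93, then SFRP2 at 0.81. Doublets are argued against by a median depth of 0.377 of that of the library. These droplets may therefore hold mostly free RNA, and no biological explanation was tested.

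MMP12, MMP1 and CXCL8 in fibroblast-like cells of peri-implantitis gingiva were weighed against free RNA and against a second fibroblast cluster. With free RNA taken off, their median log2 ratio was 8.87, which is that of CXCL8 and rests on a healthy level the correction set to 0.0 CPM. With it taken off in peri-implantitis cells alone, CXCL8 was at 44.3 and 4666 CPM, a ratio of 6.43, and MMP1 at 49.3 and 8162 CPM, a ratio of 7.11. MMP12 was at 0.6 and 9574 CPM. The correction could hardly lower these genes, which were named only if they reached 10% of the highest class. It therefore decides little about RNA from other classes. What the levels show is that MMP12 and MMP1 were highest in these cells among the named classes of that library. CXCL8 stood at 12.8% of its highest class. Within cluster 5, which holds most healthy fibroblast-like cells and 158 cells of peri-implantitis gingiva, the median with free RNA taken off was -0.079, with MMP12 and CXCL8 at 0.6 CPM or less in both libraries. As counted, the ratios in that cluster were 4.27 for MMP12, 1.94 for MMP1 and 2.97 for CXCL8, so the answer within it depends on the correction. A fibroblast state and a separate kind of fibroblast cannot be told apart, also because these same genes lead the clusters and help to draw them. The reason about the clusters was set down after the value was seen. The condition remains an open, untested explanation.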

How the results depend on the processing

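Of the alternatives, the naming margin, shares of named cells, free RNA taken off and list members at 10% or more of the highest class were chosen after the data were examined. No paired analysis was possible because there is 1 dog, with 1 library per group. The mitochondrial alternatives (20% and 10%) were not run, since no feature is mitochondrial.

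Neutrophil-like and plasma cell-like shares kept their direction in both tissues under every share alternative, from 8.94 to 32.0 and 6.65 to 24.2 points in gingiva and from -47.5 to -33.8 and 24.9 to 38.6 points in bone. Endothelial-like and B cell-like shares were lower on the peri-implantitis side throughout, and the fibroblast-like share of bone higher, at 7.46 to 71.8 points. Against the interval of the main value, 226 share values stayed within, 121 moved beyond it and 14 reversed. Of the list medians, 431 stayed outside the random lists, 28 came within and 1 reversed; of the gene ratios, 1149 stayed within their interval, 635 moved and 7 reversed.

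The values that moved or reversed follow as percentage points, peri-implantitis minus healthy, with the ending -like left out. With a minimum of 500 genes per cell, gingiva differed by -6.06 (B cell), -10.1 (endothelial), -22.5 (epithelial), 0.657 (fibroblast), -0.028 (mast cell) and 0.962 (all haematopoietic). That minimum gave -5.88 (B cell), -4.33 (T cell), 21.5 (fibroblast), -1.30 (mast cell), -33.8 (neutrophil), 29.4 (plasma cell), 14.9 (fibroblast and osteoblast as 1 class) and -6.78 (all haematopoietic classes) in bone. With shares taken of immune cells for immune classes and of non-immune cells for the others, gingiva differed by -22.0 (B cell), -5.30 (NK), 0.447 (Schwann), -30.1 (T cell), -3.31 (endothelial), -12.4 (epithelial), 4.91 (fibroblast), 0.246 (mast cell), 11.5 (mural), 32.0 (neutrophil), 0.729 (osteoblast), 0.738 (osteoclast) and 24.2 (plasma cell). These denominators gave -6.50 (B cell), 2.10 (NK), -2.33 (Schwann), 4.36 (T cell), -26.6 (endothelial), 0.989 (epithelial), 71.8 (fibroblast), -1.70 (lymphatic), 9.65 (macrophage), -3.31 (mast cell), -7.50 (mural), -47.5 (neutrophil), -34.6 (osteoblast), 2.64 (osteoclast), 38.6 (plasma cell) and 37.1 (fibroblast and osteoblast as 1 class) in bone. With shares taken of cells in named classes, gingiva differed by -0.716 (NK), -5.49 (T cell), -6.62 (endothelial), -13.3 (epithelial), 1.11 (fibroblast), 0.865 (macrophage), 6.42 (mural), 13.2 (neutrophil), 0.452 (osteoblast), 9.93 (plasma cell) and 13.2 (all haematopoietic). Named cells as the total gave 21.7 (fibroblast), 6.71 (macrophage), 27.0 (plasma cell), 15.3 (fibroblast and osteoblast as 1 class) and -7.25 (all haematopoietic classes) in bone. With doublets removed by rate in every library, gingiva differed by 0.0 (Schwann), -16.2 (endothelial), -0.407 (mast cell), 10.3 (neutrophil), 0.0 (osteoblast) and 4.38 (all haematopoietic). This doublet rate gave 0.0 (Schwann), -5.01 (endothelial), 15.8 (fibroblast), 5.50 (macrophage), 0.437 (mast cell), -40.5 (neutrophil), 0.0 (osteoblast), 1.24 (osteoclast), 26.2 (plasma cell) and 15.8 (fibroblast and osteoblast as 1 class) in bone. With resolution 0.5, gingiva differed by 0.0 (Schwann), -16.2 (endothelial) and 0.997 (macrophage). Resolution 0.5 gave -0.832 (NK), 0.0 (Schwann), 1.67 (T cell), 4.65 (macrophage), -2.08 (mast cell), 30.8 (plasma cell) and -5.79 (all haematopoietic classes) in bone. With 4000 variable genes, gingiva differed by 0.0 (Schwann), -6.37 (endothelial), -22.3 (epithelial), 1.58 (fibroblast) and 9.81 (neutrophil). 4000 genes gave 0.0 (Schwann), -3.56 (endothelial), 0.005 (epithelial), 18.9 (fibroblast), 5.56 (macrophage), -38.0 (neutrophil) and 2.67 (osteoclast) in bone. With doublets kept, gingiva differed by -17.1 (endothelial) and -0.094 (mast cell). Keeping doublets gave -1.91 (mast cell) in bone. With resolution 2, gingiva differed by -5.35 (endothelial), -24.7 (epithelial), 1.82 (fibroblast), -0.356 (mast cell), 0.070 (osteoblast), 8.62 (plasma cell) and 4.77 (all haematopoietic). Resolution 2 gave -0.807 (NK), 1.38 (T cell), 11.5 (fibroblast), 4.23 (macrophage), -1.86 (mast cell), 2.08 (osteoblast) and -12.5 (all haematopoietic classes) in bone. With each library clustered on its own, gingiva differed by -2.42 (endothelial), 0.685 (epithelial), 1.74 (fibroblast), -0.278 (mast cell), 9.87 (neutrophil), 0.0 (osteoblast) and 4.24 (all haematopoietic). Separate clustering gave -0.671 (NK), 7.46 (fibroblast), -0.279 (mast cell), -38.5 (neutrophil), 3.59 (osteoblast) and 18.7 (fibroblast and osteoblast as 1 class) in bone. With the naming margin off, gingiva differed by 6.63 (epithelial), 10.5 (neutrophil) and 4.36 (all haematopoietic). Dropping the margin gave 30.1 (plasma cell) and -5.34 (all haematopoietic classes) in bone. With no filter on barcodes, gingiva differed by -0.414 (mast cell). Dropping the filter gave -1.78 (mast cell) and -8.91 (all haematopoietic classes) in bone. A difference of 0.0 is one where no cell of the compared libraries took that name. Fibroblast and osteoblast as 1 class also counts any cells that an alternative named marrow stromal-like. For all haematopoietic cells the immune denominator was left out, since it gives 100% by construction. Changes of denominator move shares by their construction. For the others the cause was not tested.

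Lists that came within the random lists, and reversals, follow as log2 ratios. Without a filter on low values the medians were -0.037 (helper, gingiva T cell), 0.085 (cytotoxic effector, bone T cell) and 0.54 (matrix crosslinking, bone neutrophil). With each library clustered on its own the values were 0.70 (CPA3, gingiva T cell, reversed), 0.049 (proliferation, bone osteoblast), 0.40 (SFRP1, bone osteoblast, reversed) and 0.23 (DKK3, bone osteoblast, reversed). Resolution 2 gave 0.10 (proliferation, bone osteoblast) and 0.13 (SFRP1, bone osteoblast, reversed), and keeping doublets gave 0.53 (helper, bone T cell). Free RNA taken off gave -0.077 (helper, gingiva T cell), -0.18 (COL5A2, gingiva endothelial, reversed), 0.55 (helper, bone T cell), 1.03 (complement, bone neutrophil), 0.92 (matrix crosslinking, bone neutrophil), 1.02 (plasma cell list, bone neutrophil), -0.14 (TXNDC5, bone neutrophil, reversed) and -1.84 (COL1A2, bone neutrophil, reversed). List members of 50 CPM or more gave 0.094 (osteoclast-regulating ligands, gingiva fibroblast, reversed), -0.44 (metallothionein, bone NK and cytotoxic), 0.97 (interferon response, bone T cell), 1.63 (complement, bone neutrophil), 1.28 (matrix crosslinking, bone neutrophil), -0.87 (WNT modulators, bone osteoblast) and 0.32 (proliferation, bone osteoblast), by leaving fewer members. A mean over cells gave -0.36 (osteoclast-regulating ligands, gingiva fibroblast) and -0.30 (metallothionein, bone T cell). TMM scaling gave 0.24 (helper, bone T cell), and median-of-ratios scaling gave 0.22 (helper, bone T cell) and -0.59 (metallothionein, bone T cell). Members at 10% or more of the highest class gave -0.35 (metallothionein, bone NK and cytotoxic), -0.34 (metallothionein, bone T cell) and 0.94 (complement, bone neutrophil), and cells thinned to 1000 UMIs gave 1.08 (matrix crosslinking, bone neutrophil) and 0.26 (proliferation, bone osteoblast). A pseudocount of 1 CPM gave 1.58 (matrix crosslinking, bone neutrophil). Some lists had under 3 members left and gave no median. With free RNA taken off, and with members at 10% or more of the highest class, these were collagens in bone neutrophil cells and granule genes in bone osteoblast cells. At 10% or more they were also matrix crosslinking in bone neutrophil cells and the cytotoxic effector list in bone T cells. At 50 CPM or more they were the cytotoxic effector list in bone T cells and proliferation in bone NK and cytotoxic cells. Apart from the smaller lists, the cause was not tested.

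Depth limits what can be read. The smallest compared classes, such as B cell-like cells of peri-implantitis bone with 124 cells, give wide intervals, and thinning left out 233 of the 458 neutrophil-like cells of peri-implantitis bone.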

Other observations

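Metallothionein transcripts, which encode metal-binding proteins, were also high in some other blood-derived classes of healthy bone, several of them small. MT1E was at 10031 CPM in 32 plasma cell-like, 8325 CPM in 160 mast cell-like and 5162 CPM in 39 macrophage and monocyte-like cells of healthy bone, and at 102 and 69.1 CPM in the plasma cell-like and macrophage-like cells of peri-implantitis bone. It was at 541 and 4.3 CPM in endothelial-like, 538 and 21.2 CPM in osteoblast lineage-like and 936 and 30.6 CPM in neutrophil-like cells of healthy and peri-implantitis bone, levels for which free RNA from the T cell-like cells is open as a source. In T cell-like cells of gingiva it was at 24.6 CPM on the healthy and 60.4 CPM on the peri-implantitis side. The plasma cell-like and macrophage-like cells of healthy bone, and the 85 endothelial-like cells of peri-implantitis bone, are fewer than the 100 cells asked of a class for ratios. These genes were singled out after their values were seen.

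TNFSF11, which encodes RANKL, was at 386 CPM (377 to 395) in fibroblast-like cells of peri-implantitis gingiva and at 99.8 CPM (95.6 to 104.2) in those of peri-implantitis bone. In osteoblast lineage-like cells it was at 75.8 CPM in healthy and 33.1 CPM in peri-implantitis bone. NK and cytotoxic-like cells of gingiva held it at 58.2 and 74.2 CPM. TNFRSF11B, which encodes its decoy receptor osteoprotegerin, was at 4.0 CPM in healthy and 4.3 CPM in peri-implantitis gingival fibroblast-like cells, at 21.3 and 60.6 CPM in mural-like cells, at 0.8 and 69.3 CPM in epithelial-like cells of gingiva, and at 32.2 and 7.2 CPM in osteoblast lineage-like cells of bone. IL17A UMIs stood at 34.4 and 62.2 CPM in T cell-like cells of gingiva and 3.1 and 40.7 CPM in those of bone, and at 1.4 CPM or less in every other class of at least 20 cells in the 4 libraries.

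Some unnamed clusters had no class among the fixed markers or mixed them. Cluster 16, with plasma cell and cell-cycle genes, held 119 cells of peri-implantitis bone and 32 to 69 of the other libraries. Cluster 32, with dendritic cell genes, held 43 cells of peri-implantitis bone and 14 of each other library. Cluster 34, led by IL1B, IL1RN and CXCL8, held 115 cells of peri-implantitis gingiva and 100 of healthy bone.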
